A study of Mus musculus with 6 samples.

How the data were processed

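Liver RNA of C57/BL6 mice was measured in 2 groups, fetal liver at embryonic day 18 and adult liver at 2 months, with 3 arrays in each group and 6 in all. Every animal is labelled male. The design text calls the replicates of each group independent experiments, and the labels do not say whether a fetal sample was 1 liver or a pool. The p-values of single probes therefore measure the spread between these samples.

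Per the labels' protocols, total RNA was cleared of ribosomal RNA, amplified with random primers into Cy3-labelled cRNA, and hybridised to a one-colour Agilent array designed by Arraystar for mouse lncRNAs, transcripts of the long non-coding class, and for coding transcripts. Per the file headers, the scans were read with Agilent Feature Extraction 11.0.1.1, and the array grid names the mouse build mm9. The deposited scanner files hold 62939 spots per array as linear intensity, and the column used was the processed signal, which per the file headers is background-subtracted and not scaled between arrays. Low signals were raised by the software to a floor, which held 20.3% to 32.3% of the probe spots on an array. The other columns used, the flags for background, saturation and outliers, are 0 or 1 per spot per the file headers.

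A table deposited by the authors for the whole series holds log2 values of 17307 probes on the same 6 arrays, with medians of 5.94 to 6.11. Its scaling is not given in the sources used here. Set against the scanner files, each column correlated with its own array at r of at least 0.999 across probes. The values differed from quantile-normalized log2 processed signals by a median of 0.0008 to 0.0023, so the scale and the direction were settled and the values are not centred. All 17307 probes were well above background on at least 3 of the 6 arrays. The table was used as an alternative source of values.

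The main values were log2 of the processed signal minus each array's 75th percentile of it, averaged over the spots of a probe. The 1439 control spots, 300 spots of 15 negative-control probes, and outlier spots (29 to 68 per array) were left out, which left 60915 probes. No spot was saturated. Probes well above background on at least 3 of the 6 arrays were tested, which were 32336 probes. Of the others, 20353 were above background on no array. Fetal and adult arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes. A probe was called at an adjusted p under 0.05 and a change of at least 2-fold. Every log2 fold change is fetal minus adult. A probe that was not well above background on any array of one group has only a bound there. Its fold is given as "at least", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The filter stated in the design text, a 2-fold change with an unadjusted p of at most 0.05, names no test. It was run on the same values as an unpaired, two-sided, equal-variance test of each probe without moderation.

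The precision of these values is limited by the number of arrays. The 75th percentile of signal was 115.7, 70.3 and 79.4 on adult arrays 1 to 3 and 74.3, 153.8 and 84.2 on fetal arrays 1 to 3. Adult arrays 1 and 2 and fetal arrays 2 and 3 shared slide 1, and adult array 3 and fetal array 1 shared slide 2. On data simulated from the measured means and spreads of 32250 probes, with 200 probes changed, the same limma test called 10% of probes changed by 1.5 on the log2 scale. It called 36% of those changed by 2, 62% of those changed by 3 and 80% of those changed by 4, with 50 probes of each size and 4 false calls. The real comparison called far more probes, 8418 of 32336, and the adjusted cutoff depends on how many probes change. These rates therefore hold for a setting with few changed probes and do not give the sensitivity of the real comparison.

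Outside the control spots, the files pair no gene with the probes, apart from 15 probes of 20 spots each that carry RefSeq mRNA accessions. All 15 matched a gene symbol in a RefSeq table for assembly GRCm38, without versions. No coordinates from that table were used, because its build differs from that of the array. Of the remaining probes, 1836 have lincRNA in their names and are taken here as the lncRNA probes, of which 434 were tested. The 15 RefSeq probes are the protein-coding probes. The other probes are known by number alone and are treated as unclassified. The fold changes of single lncRNA probes are given for only 4 probe names, the strongest 2 in each direction among called probes well above background on all 6 arrays. All 15 RefSeq genes were named because no other probe outside the controls has a gene name.

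The groups, tests, thresholds, alternatives, 30 gene lists and rule for naming genes were fixed before the data were examined. The rule took the strongest called members of each list, a fixed set of genes including Afp, Alb, H19 and the sex-linked genes, and the strongest lncRNA probes. Of all list members, 1 gene, Tfrc of the erythroid list, was a named probe, and a list needed 5 tested genes. The list tests, the check of sex and age labels by gene, the comparison of lncRNAs with their neighbouring genes and the count without cell-type genes were therefore not made. The fixed set of genes was not analysed here. Alternatives covered scaling, background correction, the authors' table, the filter on dim probes, an intensity trend, array weights, the replicate number or the slide as a block, the fold threshold, and leaving out each array. The files have no mean-signal column, so normexp (offset 50) was run on the median spot and background signals instead, also without the offset. These runs, slide 1 alone, and the counts by membership in the authors' table were chosen after seeing the data. Comparisons between groups of probes were not among the tests fixed beforehand.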

Results

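The 6 arrays compared mouse liver at embryonic day 18, when the organ also makes blood cells, with adult liver at 2 months, with 3 arrays in each group. The question set by the design was which lncRNAs differ in level between the stages. Of the 60915 probes, from 27427 on adult array 2 to 36944 on fetal array 2 (60.6%) were well above background. Genes and probe groups are described relative to each array's 75th percentile of signal.

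Among the 15 genes with RefSeq probes on this array, Tfrc, Tuba1b and B2m changed. Tfrc, the transferrin receptor through which cells take up iron and a member of the erythroid list, was 12.3-fold higher in fetal liver. Its level was 8.12 ± 0.15 in fetal and 4.50 ± 0.23 in adult liver on the log2 scale (mean ± SD, n = 3 each). Tuba1b, an alpha-tubulin of the microtubules, was 6.94-fold higher in fetal liver, at 10.25 ± 0.39 against 7.46 ± 0.21. B2m, the light chain of MHC class I molecules on the cell surface, was 6.73-fold lower in fetal liver, at 6.78 ± 0.32 against 9.53 ± 0.21.

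For these genes, limma gave log2 fold changes of 3.62 for Tfrc (SE 0.25, adjusted p = 1.8e-04), 2.79 for Tuba1b (SE 0.29, adjusted p = 9.2e-04) and -2.75 for B2m (SE 0.28, adjusted p = 7.8e-04). All 3 genes kept their calls when p was adjusted over the 15 genes alone. On slide 1 the log2 fold changes of Tfrc, Tuba1b and B2m were 3.46, 2.46 and -2.65. On slide 2, with 1 array of each group, they were 3.95, 3.47 and -2.94.

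The other 12 genes did not pass the test. Hsp90ab1, a cytosolic chaperone, came nearest, with a log2 fold change of -0.78 (95% interval -1.44 to -0.12, limma adjusted p = 0.081) and no overlap between the groups. Ldhal6b, a lactate dehydrogenase-like gene, stood at -0.89 (interval -1.92 to 0.15). Its level on fetal array 1 was -2.14, against -0.56 and -0.87 on the other fetal arrays. Hprt, of purine salvage, stood at 0.57 (interval -0.01 to 1.16), G6pd2 at 0.47 and the ribosomal protein gene Rpl13a at 0.38. The glycerol kinase gene Gk stood at -0.37 and the lysosomal enzyme gene Gusb at -0.39. Actb, encoding a cytoskeletal actin, stood at 0.30 and Tbp, encoding the TATA-binding protein, at 0.31.

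Ppia, a cyclophilin, Gapdh, of glycolysis, and Nono, an RNA-binding protein gene, lay closest to 0, at -0.05, -0.10 and -0.14. The signs of Ppia and Gapdh turned with quantile normalization, and both intervals reached more than 0.5 to either side. In 9 of the 15 genes the fetal and adult arrays did not overlap, where chance gives 10% of genes for 3 arrays against 3. Differences were common across the array, with 13083 of the 32336 tested probes at an unadjusted limma p under 0.05. The share of all probes without overlap is not given here, so the 9 genes do not set these genes apart. The arrays' separate 3′ and 5′ probes for Gapdh gave a 5′ minus 3′ difference of -2.95 on fetal array 1, between the -3.39 and -2.33 of the other arrays. For Pgk1 that difference was -7.84 on fetal array 1, where 0.5 of the 5′ spots were above background, -6.97 on both other fetal arrays and -8.36 to -7.63 on the adult arrays.

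**Figure D1:**
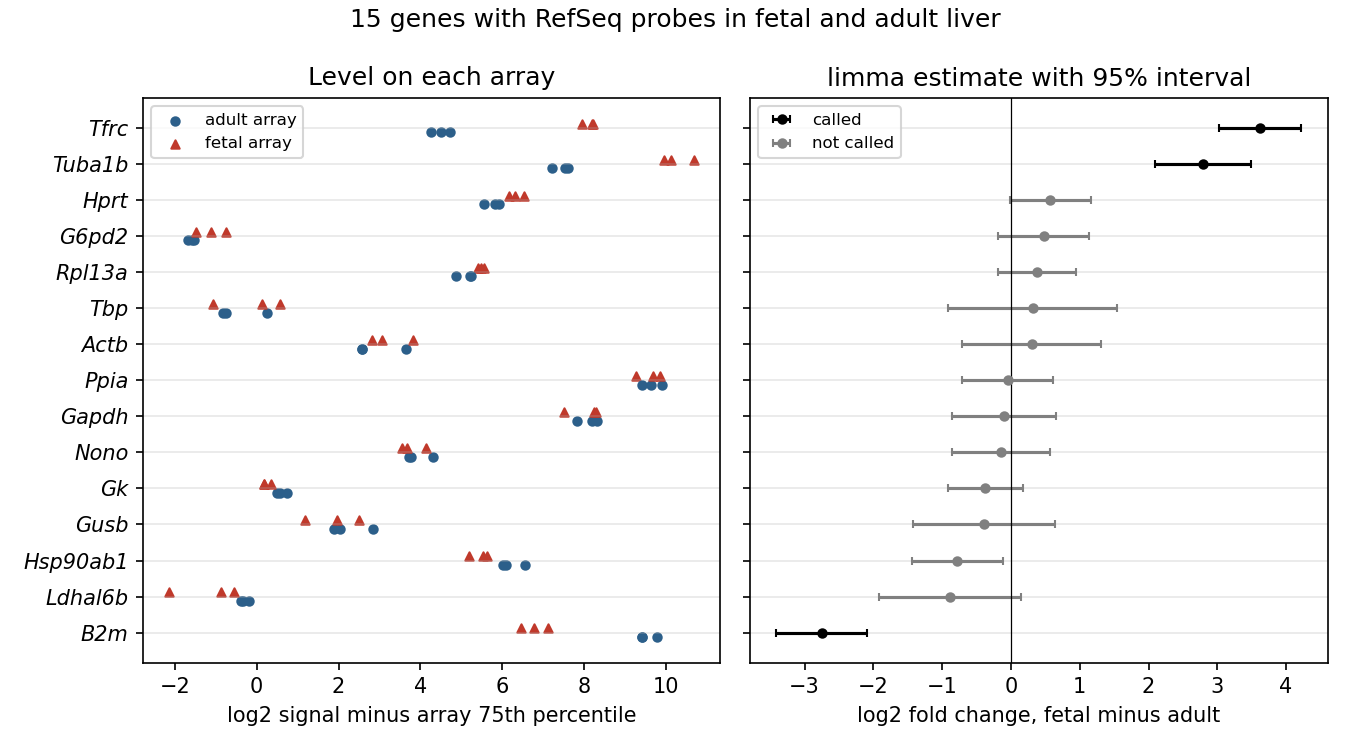
Levels of the 15 named genes on each array (left, log2 signal minus the array's 75th percentile; circles adult, triangles fetal) and limma's log2 fold change, fetal minus adult, with its 95% interval (right, black where called). Tfrc at 3.62, Tuba1b at 2.79 and B2m at -2.75 stand clear of 0.

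The lncRNA comparison rests on the 434 tested probes with lincRNA in their names, and any lncRNA probes known by number alone are not counted in it. Of these lncRNA probes, 85 (19.6%) changed, against 26.0% of all tested probes, with 33 higher and 52 lower in fetal liver. The shares were not matched for probe level. On probes above background on all 6 arrays, 28 lincRNA probes and 5213 of all probes were called. Adjusted over the lincRNA probes alone, 79 were called. At an unadjusted p under 0.05 there were 137. Of the probes named mouselincRNA 41 of 159 changed (14 higher, 27 lower), of those named humanlincRNA 37 of 244 (17 higher, 20 lower), and of those named MM9LINCRNAEXON 7 of 31 (2 higher, 5 lower). Against the rest of the probes in the authors' table, the odds ratio for a call among lincRNA probes was 0.747 (Fisher's exact test across probes, which are not independent, p = 0.0174, adjusted over 3 comparisons 0.0174). By the same exact test this difference did not hold with the slide as a block (odds ratio 0.858, p = 0.183) or on slide 1 alone (odds ratio 0.876, p = 0.266). The odds ratio for a call among humanlincRNA against mouselincRNA probes was 0.515 (Fisher's exact test across probes, p = 0.0099, adjusted over 3 comparisons 0.0148). By that exact test it did not hold with the slide as a block (59 and 47 called, odds ratio 0.761, p = 0.248) or on slide 1 alone (47 and 41 called, odds ratio 0.687, p = 0.139). Neither comparison of probe groups was among the tests fixed beforehand. The exact tests take probes as independent, so their p-values do not measure the spread between samples.

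The files do not pair these lncRNA probes with genes. The probe mouselincRNA0939+_P1 was 40.7-fold lower in fetal liver, at 0.37 ± 0.63 against 5.71 ± 0.15 (SD, n = 3 each; limma adjusted p = 1.7e-04). The probe MM9LINCRNAEXON11712-_P1 was 29.7-fold lower (limma adjusted p = 3.9e-04). The probe humanlincRNA0970-_P1 was 22.4-fold higher in fetal liver, at 3.06 ± 1.26 against -1.42 ± 0.33 (limma adjusted p = 0.0028). The probe humanlincRNA2266-_P1 was 20.2-fold higher (limma adjusted p = 0.0189). Its call was lost without adult array 1 (adjusted p = 0.0675) and without adult array 2 (0.0682). Without fetal array 1 the log2 fold changes of humanlincRNA0970-_P1 and humanlincRNA2266-_P1 went from 4.48 and 4.34 to 3.77 and 3.25, and without fetal array 2 the latter went to 4.94. With normexp and the 75th percentile the log2 fold changes of humanlincRNA0970-_P1 and mouselincRNA0939+_P1 were 3.14 and -4.71, and with array weights that of humanlincRNA2266-_P1 was 3.28. On slide 1 the log2 fold changes of the 4 probes in the order named were -5.62, -4.41, 3.59 and 3.80, and on slide 2 they were -4.79, -5.85, 6.28 and 5.41.

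Of the tested lincRNA probes, 25 were above background on all 3 fetal arrays but on no adult array, and 17 of them were called. The reverse held for 15 lincRNA probes, of which 14 were called. The arrays differed in how many probes they detected, so these counts do not compare the stages alone. Of the called ones, 12 on the fetal side and 11 on the adult side had a bound of at least 2-fold. The strongest of these lincRNA probes was at least 18.8-fold higher in fetal liver, and the strongest on the adult side at least 4.98-fold higher in adult liver. With the slide as a block 115 lincRNA probes were called, and on slide 1 alone 101. The higher group grew from 33 to 51 with that block, and on probes above background on all 6 arrays 28 lincRNA probes were called. Normexp with the 75th percentile called 26 (13 higher, 13 lower), and array weights called 137 (60 higher, 77 lower). Without adult array 1, 2 or 3 the higher group fell from 33 to 21, 21 and 20 lincRNA probes.

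Of all 32336 tested probes, 8418 (26.0%) changed, 3639 higher and 4779 lower in fetal liver. The change was at least 4-fold for 4454 probes and at least 16-fold for 1139, of which 567 were higher and 572 lower. These counts use limma's estimates, including those of probes with only a bound in one group, so some sizes were not measured. Of the called probes, 5119 were above background on all 6 arrays and 1549 on no array of one group. The median log2 fold change of all tested probes was -0.06. Probes above background on fetal arrays alone numbered 1335, with 1053 called, and those on adult arrays alone numbered 504, with 496 called. An adult-only probe had to be missed on fetal array 2, which detected the most probes (36944). It also had to be seen on adult array 2, which detected the fewest (27427). These counts therefore do not compare the stages alone. Among called probes above background on fetal or on adult arrays alone, the bound was at least 2-fold for 678 and 434. For the other such calls a 2-fold change is not secured. Bounds reached at least 3007-fold on the fetal side and at least 24757-fold on the adult side.

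**Figure D2:**
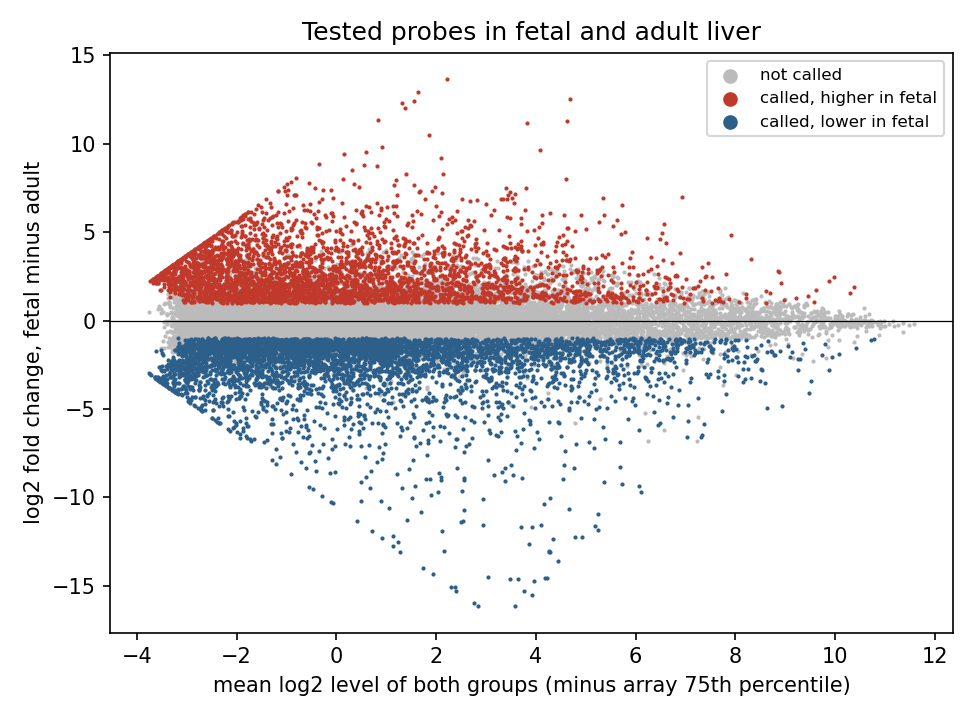
Each point is 1 of the 32336 tested probes, by its mean log2 level over both groups (relative to the array's 75th percentile) and its log2 fold change, fetal minus adult. The 3639 probes called higher and the 4779 called lower in fetal liver are coloured, and the oblique edges at the left come from probes at the floor in one group.

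Probes listed in the authors' table and the other tested probes split differently by direction. Of the 17307 listed probes 4233 changed, 2034 higher and 2199 lower in fetal liver (48.1% higher). Of the 15029 others 4185 changed, 1605 higher and 2580 lower (38.4% higher). The odds ratio for the fetal side was 1.49 across probes, which are not independent. This split, 1 of the 3 comparisons, was chosen after the data were seen, so its p is left out. The listed probes included all 434 tested lincRNA probes and none of the 15 RefSeq genes. Of the called lincRNA probes 38.8% were higher in fetal liver, with an odds ratio of 0.681 against the rest of the listed probes (Fisher's exact test across probes, p = 0.0997, adjusted over 3 comparisons 0.149). This comparison was also not among the tests fixed beforehand. With the slide as a block the fetal-side shares of listed and other probes were 50.5% and 39.7%, and on slide 1 alone 50.7% and 41.4%. They lay closest without adult array 1, at 45.7% and 40.4%. Without fetal array 3 they were 45.9% and 39.0%, and with the replicate block 46.7% and 39.7%. They lay farthest apart without fetal array 2, at 47.8% and 35.5%. Without adult array 1, 2 or 3 the listed probes called higher numbered 1316, 1260 and 1258, and those called lower numbered 1413 without adult array 2 and 1461 without adult array 3. The filter of the design text, without moderation or adjustment, passed 8704 probes (3710 higher, 4994 lower), 4400 of them listed, and 93 lincRNA probes. Of these 8704, limma called 8323, and 5681 passed after Benjamini-Hochberg adjustment. That last count fell to between 2234 and 2918 when any array but fetal array 1 was left out.

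Both stages shared both slides. With the slide as a block limma called 10122 probes (4570 higher, 5552 lower), of which 8408 were among the 8418. On slide 1 alone, with 2 arrays of each group, it called 8756, of which 7229 were shared. Slide 2 holds 1 array of each group and allows no test. Of the 8752 probes called on slide 1 alone with a value on slide 2, 82.8% differed there by at least 2-fold in the same direction and 1.91% in the opposite one, against 29.2% and 5.87% of the 23543 probes not called on slide 1. Fewer probes were called without adult array 2 (5312, with 2284 higher and 3028 lower) or adult array 3 (5396, with 2259 and 3137), the 2 arrays whose removal moved the count by over 1.5 times.

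Fetal array 1 stood apart from the other fetal arrays. Across 32250 probes with a value on every array, the adult pairs correlated at r of 0.967 to 0.983. Fetal arrays 2 and 3 correlated at 0.983, while fetal array 1 correlated with them at 0.893 and 0.915. Fetal with adult arrays gave 0.709 to 0.845, with the lowest values for fetal array 1. Probes are not independent replicates, so these values describe the arrays only. Leaving out fetal array 1 raised the number of called probes to 10021 (7897 shared with the 8418) and that of lincRNA probes to 112, and left Tfrc, Tuba1b and B2m called.

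**Figure D3:**
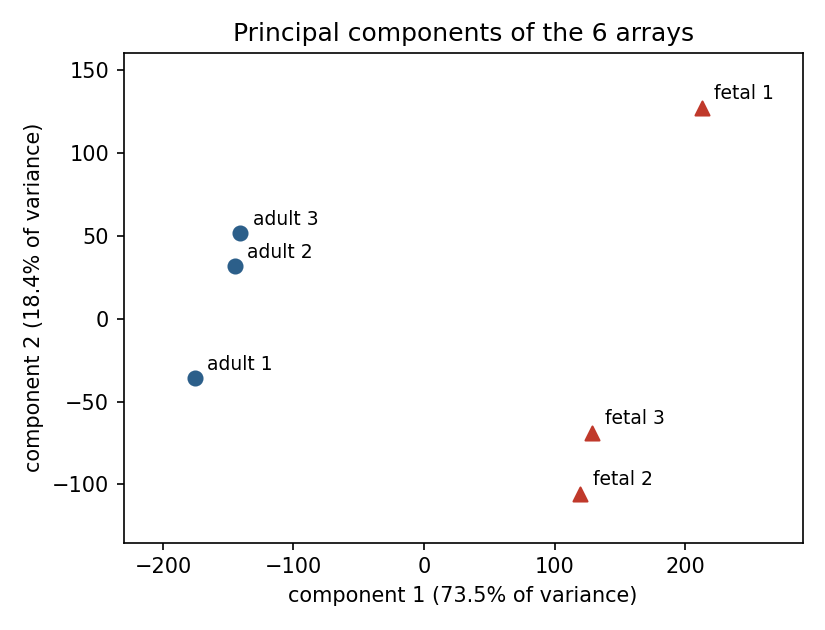
Principal components of the 6 arrays over the tested probes, with circles for adult and triangles for fetal arrays. Component 1 (73.5% of variance) separates the groups, and fetal array 1 lies at 213 on it and at 127 on component 2 (18.4%), against 120 and 129, and -106 and -69, for fetal arrays 2 and 3.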

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

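The tests of slide, distance from adult liver and spiked RNA described here were chosen after the results were seen, as was the split by the authors' table. The bounds of the tests on bright probes and on probe level, and the splits of the arrays, were set before their values were seen.

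Control probes that target no mouse gene were looked at because they lie outside the comparison. Of 53 such probes, 2 of the adenoviral E1A set were above background in most of their spots on all 3 fetal arrays, lay higher there than on every adult array, and exceeded the negative controls. The probe (+)E1A_r60_a107 had log2 levels of 7.62, 4.22 and 5.42 on fetal arrays 1 to 3 and -3.09, -0.27 and -0.56 on adult arrays 1 to 3, a difference of 7.06, fetal minus adult. The probe (+)E1A_r60_a97 differed by 2.40. These differences are not exact, since on adult array 1 only 0.171 and 0.0286 of the spots of these probes were above background, and on adult array 2 only 0.543 of those of (+)E1A_r60_a97.

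One candidate explanation for the E1A signal is a spiked control RNA added to the fetal samples. If such a mix lit up most of the set, more probes would be bright than were seen. Of the 10 E1A probes, 3 were above background in most spots of all fetal arrays, where at most 5 had been set as the bound against it. The probe (+)E1A_r60_3, 1 of these 3, was about as bright on the adult arrays (difference -0.06). The amounts in such a mix are not given, and unequal amounts could leave some probes dim, so the count cannot decide on a spike. Binding of a fetal liver transcript to (+)E1A_r60_a107 and (+)E1A_r60_a97 also stays open and was not tested.

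A slide effect could account for the distance of fetal array 1 from fetal arrays 2 and 3, since fetal array 1 and adult array 3 shared slide 2 and their deviations from their groups correlated at 0.48 across probes, but this r ranged from -0.35 to 0.65 among pairs on slide 1 and the deviation of adult array 3 was only 0.429 times as large, below the bound of 0.5, which argues against the slide as the whole cause. Noise in dim probes predicts similar fetal arrays among bright probes, but in the brightest 25% of probes fetal array 1 lay 3.38 times as far from fetal arrays 2 and 3 as these lay from each other. A fetus further from the adult state could differ along the fetal-adult axis, and fetal array 1 did lie at 213 on component 1, against 120 and 129, and farther from the adult mean than fetal array 2 at 62.8% of called probes. However, an axis was built without it, from the adult mean at 0 to the mean of fetal arrays 2 and 3 at 1. On that axis fetal array 1 lay at 1.02, or at 1.09 in the brightest 25% of probes. Fetal 1 minus fetal 3 correlated with fetal 2 minus adult at 0.0182 across all probes (interval 0.0057 to 0.0326), below the bound of 0.1. In the brightest 25% that r was 0.101 (interval 0.0687 to 0.135). Both measures also take in component 2, where fetal array 1 lay at 127, fetal arrays 2 and 3 at -106 and -69, and adult arrays from -36 to 52. Differences on component 2 can offset those on component 1, so these values cannot decide whether fetal array 1 was further from the adult state. A fault of that array or RNA sample and a difference between fetuses in other directions also stay open.

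Called probes of the authors' table were higher in fetal liver more often than other called probes. The listed probes were dimmer (median level of called probes -0.65 against 0.56), which could shift directions. With called probes compared within 10 bins of level, the odds ratio was still 1.38 (95% interval 1.27 to 1.51), above the bound of 1.1. Binning by level thus removed only part of the difference on these arrays. Levels can still differ within a bin and come from the same values as the calls, so the test cannot exclude probe level. The interval takes probes as independent, which they are not, and does not measure the spread between samples. Whether lncRNAs carry the split is not settled by the probes named as lincRNA, all of them listed. In the main fit 38.8% of their calls were on the fetal side, against 38.4% outside the table. With the slide as a block these shares were 44.3% and 39.7%. With normexp and the 75th percentile 13 of their 26 calls were on the fetal side, against 37.0% outside the table. In the main fit no difference was shown from the rest of the listed probes (odds ratio 0.681, Fisher's exact test, p = 0.0997). The listed probes could be the lncRNA part of the array, since they include all 434 tested lincRNA probes and none of the 15 RefSeq genes, in which case the split would set lncRNAs against other transcripts, but no source used here says so.

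The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each count, 1 split, the real one, gave as many calls. By limma the real split called 8418 of all probes, 85 lincRNA probes, 3 RefSeq genes and 4233 listed probes, and the highest of the other splits called 0 in each case. The filter of the design text passed 8704 probes in the real split and at most 1286 in another. Every other split puts fetal and adult arrays in both groups, so the stage difference widens the spread within them. Low counts in those splits follow from this and do not speak on chance.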

How the results depend on the processing

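The normexp runs, slide 1 alone and the counts of listed probes were added after seeing the data, and the other alternatives were fixed before. Tfrc, Tuba1b and B2m kept their calls and directions under all 19 settings run on them. The fetal share of all calls ran from 38.9% to 49.3%. Of the counts under alternatives 155 stayed within 1.5 times the main one, 69 were lower and 5 higher by more. Of the values of named genes and probes 348 kept their direction and side of the threshold, 14 changed sign and 3 lost a call. Normexp without its offset called 7654 probes and 76 lincRNA probes, so most of the fall with the offset of 50 came with that offset. A stricter filter, a higher fold threshold or the authors' table takes in fewer probes. The cause of the other shifts was not tested. Signal over background limits the 9488 tested probes that were not above background on all arrays.

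With normexp and the 75th percentile, 4562 of all probes were called (1906 higher, 2656 lower), 26 lincRNA probes (13 and 13), and listed probes 965 higher and 1056 lower. The design filter passed 4700, or 2959 after adjustment. With normexp and quantiles these were 4548 (1913, 2635), 25 (12, 13), 970 and 1045, 4756 and 3486. The authors' table values gave 4250 (2097, 2153), and 4456 and 2891 for the design filter. Probes above background on all 6 arrays gave 5213 (2027 higher), 28 lincRNA probes (10, 18), listed probes 1067 and 1307, and 5331 and 3516 for the design filter. Array weights raised the higher group to 5703, listed probes higher to 3270, and lincRNA probes to 137 (60 higher). With the slide as a block 51 lincRNA probes were higher. At 4-fold, 4454 remained (2154, 2300), with 31 lincRNA probes lower and listed probes 1187 and 1054. The design filter after adjustment gave 1134 on slide 1 alone.

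Same-numbered arrays did not deviate together (r of -0.53, -0.35 and -0.31 across probes), and none deviated most like its own number. These values show no sign of a pairing by number. They cannot exclude one, because the deviations within a group depend on each other and fetal array 1 stood apart. With the replicate block 4506 probes were called (1947, 2559), 51 lincRNA probes (16 higher), and listed probes 1059 and 1211. Here the design filter was run as a paired test of arrays with the same number, not as the unpaired test. It passed 5716, or 6 after adjustment. The block ended the call of humanlincRNA2266-_P1 (limma adjusted p = 0.0605, over all settings 0.000254 to 0.0682) and of no other named gene or probe.

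Leaving out each array in turn gave 5312 to 10021 called probes (2259 to 4675 higher, 3028 to 5346 lower), and 20 to 42 lincRNA probes higher. Listed probes ran from 1258 to 2639 higher and from 1413 to 2490 lower, and the design filter after adjustment from 2234 to 6223. Among genes that were not called, Ppia turned to 0.117 with quantiles, 0.0200 and 0.114 with normexp, 0.0675 with array weights, and -0.18 to 0.11 without single arrays. Gapdh turned to 0.0720 with quantiles, 0.0697 with normexp and quantiles, 0.101 with array weights, 0.0111 on slide 1, and -0.24 to 0.16 without single arrays. Nono ran from -0.32 to 0.0490 and Tbp from -0.0332 to 0.79 without single arrays. Not run were normexp on mean signals, the composition count, and every alternative of the gene lists and of lncRNA neighbours, since these need columns or gene names not used here.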

Other observations

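The ASMM10UP probes were singled out after their counts were seen, so the test of their direction that was run afterwards on the same arrays is void and its p is left out. Of the 240 tested probes whose names begin with ASMM10UP, all listed in the authors' table, 50 changed, 35 higher and 15 lower in fetal liver (70% higher, against 48.1% of all listed probes that changed). On the same arrays, with the slide as a block 42 were higher and 18 lower, and on slide 1 alone 42 and 15. What sets these probes apart on the array is not given in the sources used here.

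Mouse Pgk1, a glycolytic enzyme gene, was read by separate control probes. Its 3′ probe had log2 levels of 5.35, 7.66 and 7.25 on fetal arrays 1 to 3 and 7.44, 6.94 and 6.81 on adult arrays 1 to 3.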
